A study of Mus musculus with 2 samples.

How the data were processed

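Retina and choroid of adult C57BL/6J mice had been digested separately in papain for 45 min, the retinal cells depleted of rods with beads against CD73, and both suspensions mixed after a 40 µm mesh and loaded at 200 cells per µL for droplet sequencing. There was 1 library per group, Smoke and Smoke_CNV, and the number of animals per library is not given in the sources used here. The submitters' processing notes name Cell Ranger, without a version, and Seurat 4.1.1 with the mouse build mm10. The gene filter and annotation release are not given in the sources used here. The deposited values were natural log values (ln) of 1 plus the UMIs of a gene per 10000 UMIs of the cell. Cells were tied to libraries by the initials of the prefix in their names (S for Smoke, SC for Smoke_CNV), which is an inference. The other 21907 cell columns of the table, with the prefixes CNV and con, matched neither library and were not used.

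UMI counts were recovered per cell. Back-transformed values summed to 10000 in every cell used, and 100% of values were whole multiples of the smallest value in their cell, within a tolerance of 1e-06. The table held 25400 genes, 287 of them with no UMI in the cells used. Cells already had at least 500 UMIs and at most 19.97% mitochondrial UMIs. Before the data were examined, the cell filter (at least 300 genes, at most 20% mitochondrial UMIs), the clustering settings, the marker lists of 28 cell types, the 21 gene lists and the rule for named genes were fixed. The filter kept 13731 of 13737 Smoke cells and 11408 of 11409 Smoke_CNV cells. Scrublet, with an expected doublet rate of 0.06, called 223 doublets in Smoke (1.62%), which were removed, and 0 in Smoke_CNV, where its threshold was 0.681, so doublet removal was unequal between the libraries. It also changed with the filter: under the stricter filter 0 doublets were called in both libraries, and with no filter 322 in Smoke and 0 in Smoke_CNV. As an alternative chosen after seeing the data, the 6% of cells with the highest doublet scores were removed in each library.

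Counts were scaled to 10000 per cell and log transformed, and 2000 highly variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (seed 0) were used, with no integration of the libraries. Each cluster was scored by the mean log2 fold of each type's markers against clusters of other families, with a pseudocount of 0.05 UMIs per 10000. A name needed a mean of at least 0.5, at least 3 markers at a log2 fold of 1, a lead of 0.5 over the second type, and at least 2 own markers among the 50 leading genes. These naming thresholds were set after the data were examined. A cluster stayed unnamed where its median depth was under 1/3 of its library's with no own marker among its 10 leading genes. It also stayed unnamed where its depth was under 50% of the library's median and under 5% of its cells came from 1 library, or where leading genes of another type prevailed. The mural cluster was clustered again (resolution 0.3, 1000 variable genes, 15 components) into pericyte-like and smooth muscle-like cells. Names carry the ending "-like" because they rest on markers alone. Macrophage, monocyte and microglia types formed 1 family, named macrophage-like, and T cell and NK cell types 1 family, named T cell-like.

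UMIs were summed per class and library and divided by the class total, on the CPM scale. Classes needed at least 50 kept cells in each library (pericyte-like, at least 20), which left 14 classes, and genes at least 20 UMIs over both libraries. Ratios are Smoke_CNV over Smoke with exact conditional binomial intervals, levels have exact Poisson intervals, and shares exact Clopper-Pearson intervals, all at 95% and for counting error only. A gene at 0 UMIs in 1 library was given as a bound against a floor of 3 counts over the class. Such a bound leaves out the counting error of the other library, and the exact lower limit is smaller (12.5 against 15.9 for Top2a in pericyte-like cells). For gene lists with at least 5 measured members, the median log2 ratio (prior of 0.5 UMIs) was placed as a percentile among 10000 random lists matched on expression in 10 bins. Its interval came from 1000 Poisson redraws. Since each group had 1 library and cells are not replicates, no p-value was computed. For shares of cells with a UMI, cells were also thinned to 2022 UMIs, the 25th percentile of kept cells, and shallower cells left out.

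For each class, 4 genes per direction were to be named by the interval bound nearest to 1, without ribosomal, mitochondrial, haemoglobin, sex-linked and crystallin genes, Malat1 and unnamed gene models. For each list described, up to 4 members with the most UMIs and 2 by ratio could be named. Sema4d and Plxnb1 were always named. The 44 pairs of class and list described were chosen after their values were seen, and the genes named by size of change in amacrine-like, bipolar-like, cone-like, smooth muscle-like, surface epithelium-like and T cell-like cells are left out for length. Results of some list members are not reported here.

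Alternatives fixed before were no cell filter, a stricter one (500 genes, 10% mitochondrial UMIs), doublets kept, Leiden resolution 0.5 and 2, shares without rod-like cells, scaling by the median ratio of genes or by the trimmed mean of M values (30% of M and 5% of A values trimmed at each end), a minimum of 50 UMIs or none, a prior of 2 UMIs, and equal weight per class for whole libraries. Free RNA was also subtracted per library at the share that rod genes allow, in 10 of the 14 classes. The added alternatives, chosen after seeing the data, were the removal of the highest doublet scores, shares without surface epithelium-like cells and unnamed clusters, the cluster of each class with the most Smoke cells, lists without the markers that name the class, and, for retinal classes, a subtraction from Smoke_CNV by fibroblast, macrophage or keratin genes and cells matched within 10% on their share of ribosomal protein UMIs.

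The procedure was tested on simulated data with 200 genes changed 2-fold, 4-fold or 8-fold. Counts were independent Poisson draws from 1 profile shared by both libraries. UMIs grouped within cells, free RNA and differences in cell mix were not simulated. The test therefore checks the computation under counting error alone, not how well intervals cover differences between these libraries. Intervals held the true ratio for 96.5% of 8796 unchanged genes in simulated pericyte-like, 96.0% of 15415 in Müller glia-like and 96.5% of 14090 in macrophage-like cells. The interval lay beyond 1 for 68.3% of 63, 98.4% of 61 and 100% of 58 genes at the 3 folds in pericyte-like cells. These shares were 80.3%, 100% and 100% of 66 genes each in Müller glia-like cells, and 75.8% of 66, 94.9% of 59 and 100% of 62 in macrophage-like cells. Medians of a simulated list of 20 genes changed 2-fold were 0.98, 0.97 and 1.02 in log2, at percentile 100. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.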

Results

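Droplet-based single-cell RNA sequencing was read for retina and choroid of adult wild-type C57BL/6J mice in 2 groups of 1 library each. Mice of both groups inhaled cigarette smoke (1.2 mg nicotine, 13 mg CO and 13 mg tar per cigarette). The Smoke library had no laser injury by its title, although both libraries carry the same treatment text. The Smoke_CNV group had laser burns (532 nm, 200 mW, 0.15 s, 100 µm), the usual mouse model of choroidal neovascularisation (CNV), and was taken on day 3. Every comparison below therefore sets laser injury against no laser injury in smoke-exposed eyes, and no group without smoke was analysed here. The Smoke library held 13737 cells with 84582582 UMIs (unique molecular counts of captured RNA), a median of 3914 UMIs and 1861 genes per cell. The Smoke_CNV library held 11409 cells with 114199556 UMIs, a median of 4967 UMIs and 2303 genes per cell. The median mitochondrial share was 1.07% in Smoke and 2.53% in Smoke_CNV. With 1 library per group there was no replicate check and no test between groups. Intervals of shares, levels and ratios are exact 95% intervals and those of list medians come from Poisson redraws. All cover counting error only, and the cells were tied to the groups by the initials that open their names.

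The first comparison asked which cell classes were recovered with and without laser injury. Immune cells made up more of the Smoke_CNV library: macrophage-like cells, a class that does not separate macrophages, monocytes and microglia, were 1.36% of 13508 kept cells in Smoke and 11.0% of 11408 in Smoke_CNV, a ratio of 8.11 (6.94 to 9.53). Dendritic-like cells were 0.341% and 1.79% (ratio 5.25, 3.80 to 7.40), neutrophil-like cells 9 and 121 cells (ratio 15.9, 8.11 to 35.7), and T cell-like cells 0.474% and 1.03% (ratio 2.16, 1.58 to 2.98). Also larger were endothelial-like cells at 2.90% and 5.74% (ratio 1.98, 1.74 to 2.25) and fibroblast-like cells at 11.5% and 17.7% (ratio 1.54, 1.44 to 1.65). Retinal classes were smaller: rod-like cells were 36.5% and 14.5% (ratio 0.396, 0.374 to 0.419), Müller glia-like cells 10.5% and 3.97% (ratio 0.379, 0.340 to 0.421) and cells like those of the retinal pigment epithelium (RPE) 4.58% and 1.71% (ratio 0.374, 0.316 to 0.440). Pericyte-like cells, the contractile cells that wrap capillaries and that the series title names, numbered 102 in each library, 0.755% and 0.894% (ratio 1.18, 0.891 to 1.57). Smooth muscle-like cells numbered 180 and 110 (ratio 0.724, 0.566 to 0.922), and at Leiden resolution 2 the ratio was 0.907 with an interval that included 1 (0.697 to 1.18), as did that of 0.963 without surface epithelium-like cells and unnamed clusters.

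A share can be set by the dissection and by the bead step that removed rods by CD73, so every ratio here is also a ratio of tissue pieces. Keratin-rich ocular surface epithelium, which is neither retina nor choroid, was 0.829% of cells in Smoke and 8.29% in Smoke_CNV (ratio 10.0, 8.22 to 12.3). Clusters that stayed unnamed held 3.76% and 20.01%, in part by thresholds set after the data were examined. The largest of these, cluster 12, held shallow cells with rod genes and was 0.193% of Smoke and 9.66% of Smoke_CNV. With no cell filter the rod-like ratio was 0.650. Without rod-like cells in the denominator, the pericyte-like ratio was 0.879 and the fibroblast-like ratio 1.14. Without surface epithelium-like cells and unnamed clusters, an alternative chosen after seeing the data, the pericyte-like ratio was 1.58.

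**Figure D1:**
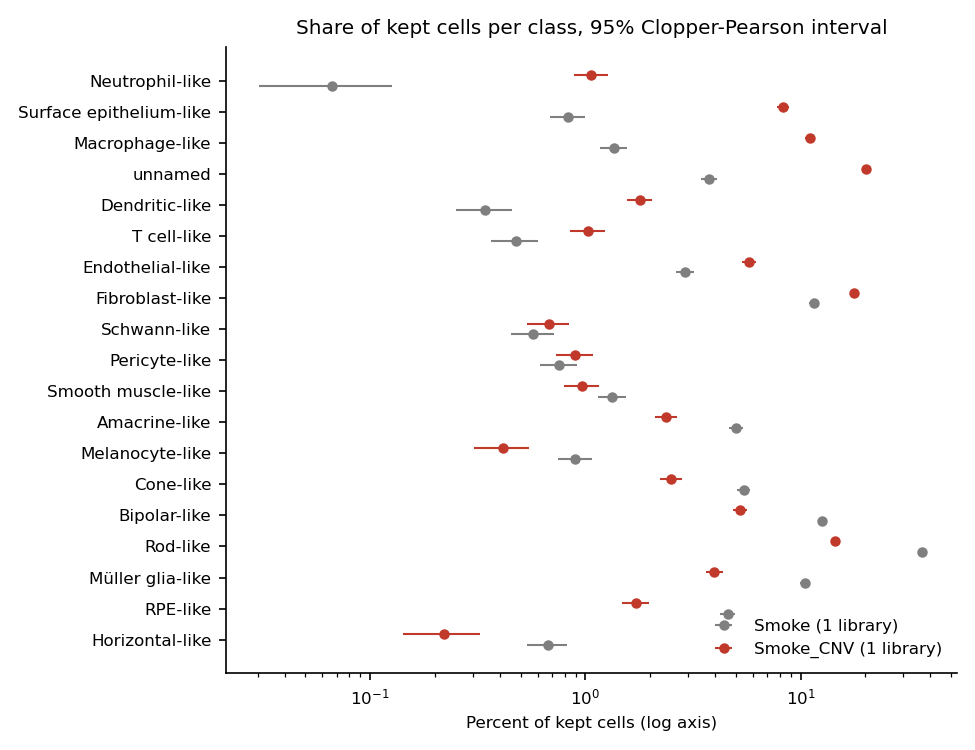
Share of kept cells per class (percent, log axis) in the Smoke and Smoke_CNV libraries, 1 library each, with exact 95% binomial intervals. Immune classes lie to the right in Smoke_CNV (macrophage-like 1.36% and 11.0%) and retinal neurons and glia to the left (rod-like 36.5% and 14.5%).

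The second comparison concerned the ligand and receptor that the series title names. Sema4d encodes semaphorin 4D, a membrane protein known from immune cells (chromosome 13, 51685529 to 51793747, minus strand, mm10, ENSMUSG00000021451.16). Plxnb1 encodes plexin-B1, its high-affinity receptor (chromosome 9, 109095389 to 109119917, plus strand, mm10, ENSMUSG00000053646.13). In Smoke_CNV the highest Sema4d levels were in neutrophil-like cells at 455 CPM (UMIs of the gene relative to all UMIs of the class; 398 to 517), T cell-like cells at 290 (246 to 340) and dendritic-like cells at 113 (102 to 125). Macrophage-like cells held 157 CPM in Smoke and 98.8 in Smoke_CNV, a ratio of 0.631 (0.556 to 0.720). Müller glia-like cells held 93.3 and 64.1 CPM, a ratio of 0.687 (0.606 to 0.778). Surface epithelium-like cells held 86.5 and 101.8 CPM, about the macrophage-like level in Smoke_CNV. Ratios with an interval above 1 were those of dendritic-like (1.51, 1.12 to 2.09), neutrophil-like (4.33, 1.83 to 13.5, from 5 UMIs in Smoke), endothelial-like (2.20, 1.23 to 4.19), bipolar-like (1.27, 1.05 to 1.54), cone-like (1.66, 1.12 to 2.45) and surface epithelium-like cells (1.18, 1.04 to 1.34). Endothelial-like cells held only 4.13 and 9.10 CPM (15 and 56 UMIs), not above rod-like cells, taken as background, at 8.24 and 9.51. Macrophage markers rose from 0.0163% to 0.144% of UMIs in endothelial-like and from 0.0112% to 0.0896% in cone-like cells. All Sema4d values here are levels per UMI of the class: the macrophage-like values came from 274 UMIs in 183 cells and 1763 UMIs in 1254 cells, at a mean depth of 9566 and 14225 UMIs per cell, so the count per cell differed less than the CPM. Pericyte-like cells had 1 Sema4d UMI in Smoke and 3 in Smoke_CNV.

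Macrophage-like cells supplied more of the library's Sema4d in Smoke_CNV, where there were more of them. They gave 9.23% of 2968 Sema4d UMIs in Smoke and 32.5% of 5430 in Smoke_CNV. Surface epithelium-like cells gave 9.64% and 31.5%, and Müller glia-like cells 43.9% and 5.76%. Summed over all kept cells, Sema4d was 36.3 CPM in Smoke and 47.6 in Smoke_CNV (ratio 1.31, 1.25 to 1.37), and with equal weight per class the ratio turned to 0.952. A Sema4d UMI was seen in 55.2% of macrophage-like cells in Smoke (median 8815 UMIs per cell) and 49.1% in Smoke_CNV (13340). With each cell thinned to 2022 UMIs these shares were 23.0% of the 174 cells deep enough and 16.8% of 1211. Rod-like cells, taken as background, had one in 2.07% (median 2222 UMIs) and 2.97% (3558), and after thinning in 1.71% of 2685 and 2.20% of 1270. Pericyte-like cells, at 0.980% (0.0248 to 5.34) and 1.96% (0.238 to 6.90), could not be told apart from that background.

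Plxnb1 was detected in pericyte-like cells of both libraries at nearly the same level, 24.8 CPM (14.9 to 38.7) in Smoke and 24.2 (15.3 to 36.3) in Smoke_CNV, from 19 and 23 UMIs. The ratio was 0.977 with an interval of 0.509 to 1.90, so a change within that range was not detectable at this depth. A Plxnb1 UMI was found in 17.6% of pericyte-like cells in each library (median 7636 and 8477 UMIs), and after thinning in 4.21% of 95 and 5.15% of 97 cells. Rod-like cells, the background taken for Sema4d, held 37.5 and 31.5 CPM of Plxnb1, with one in 7.11% of 2685 and 6.22% of 1270 thinned cells, so pericyte-like Plxnb1 was not above that class. Endothelial-like cells, which had little Plxnb1, showed one in 4.34% and 4.58% of cells (median 7588 and 6240 UMIs), and after thinning in 0.302% of 331 and 1.10% of 547. Smooth muscle-like cells held 31.0 and 27.8 CPM, and Müller glia-like cells 62.7 and 66.0. RPE-like cells held 37.4 and 53.3 CPM (ratio 1.43, 1.01 to 1.98), while macrophage-like cells held 2.86 and 2.52. Plxnb2, a second plexin that binds semaphorin 4D, was higher in fibroblast-like cells (36.1 and 59.9 CPM, ratio 1.66, 1.51 to 1.83) and in Müller glia-like cells (37.4 and 61.5, ratio 1.64, 1.42 to 1.90), but also in most other classes, among them rod-like (ratio 2.20, 1.59 to 3.03), bipolar-like (2.03), cone-like (2.02) and endothelial-like cells (1.81), so it was not particular to these. In pericyte-like cells Plxnb2 was 78.3 and 74.7 CPM (ratio 0.955, 0.667 to 1.37).

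**Figure D2:**
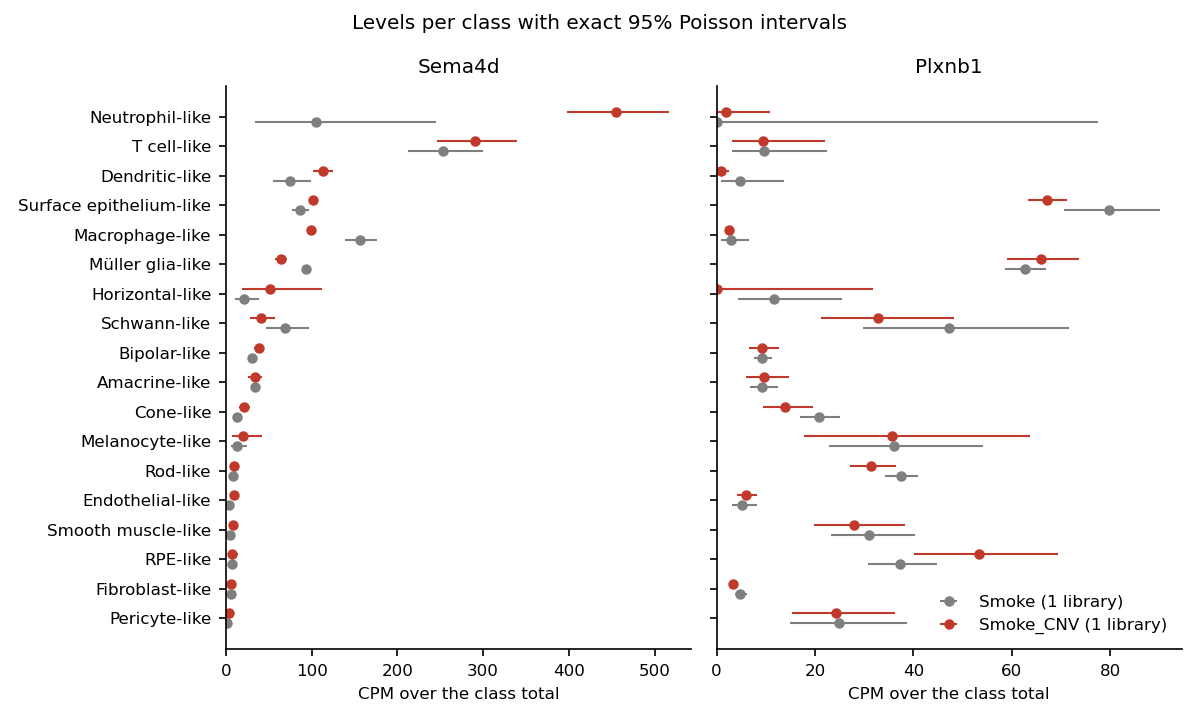
Sema4d and Plxnb1 in CPM of each class, in the Smoke and Smoke_CNV libraries (1 each), with exact 95% Poisson intervals. The highest Sema4d levels are in lymphoid and myeloid classes, but surface epithelium-like cells hold 86.5 and 101.8 CPM and Müller glia-like cells 93.3 and 64.1. Sema4d is near 0 in pericyte-like cells, whose Plxnb1 is 24.8 and 24.2 CPM.

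The third comparison asked what pericyte-like cells expressed differently after laser injury. Matrix and activation genes were higher: 14 of 16 measured members of the pericyte activation and contraction list were higher and 2 lower, with a median log2 ratio of 1.04 (0.76 to 1.19), at percentile 100 of 10000 random lists matched on expression. Col3a1, a fibrillar collagen, was 631 CPM in Smoke and 1114 in Smoke_CNV (ratio 1.76, 1.58 to 1.97). Fn1, fibronectin, had a ratio of 9.41 (4.11 to 26.5) from 6 and 70 UMIs, and Tnc, tenascin C, a ratio of 12.1 (3.07 to 104) from 2 and 30 UMIs. The receptor gene Pdgfrb, which names pericytes, was close to level at 968 and 1008 CPM (ratio 1.04, 0.945 to 1.15). The 2 lower members were Myl9, myosin light chain, at 0.845 (0.747 to 0.956) and Ccn2, a matricellular growth factor, at 0.408 (0.357 to 0.465). Of the extracellular matrix list 20 of 21 members were higher (median log2 0.82, percentile 100), among them Col4a1, a basement membrane collagen, at 1.66 (1.50 to 1.85) and Col6a3 at 6.05 (3.11 to 13.1), while Dcn, decorin, was lower at 0.675 (0.592 to 0.769). Fibroblast marker genes made up 1.22% of the UMIs of pericyte-like cells in Smoke and 1.46% in Smoke_CNV. The activation median was 0.30 with free RNA, estimated from rod genes, subtracted, and 0.67 over members with at least 50 UMIs. The matrix median was 0.43 after that subtraction, Fn1 then had 0 UMIs in Smoke_CNV, and the Tnc ratio was 1.17.

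Genes of vessel growth signals and of the interferon response were lower in pericyte-like cells. Of the angiogenesis list 10 of 11 measured members were lower, 6 of them with an interval below 1, with a median log2 ratio of -0.33 at percentile 1.86. Pgf, placental growth factor, had a ratio of 0.586 (0.444 to 0.772), Angpt2, angiopoietin 2, 0.633 (0.447 to 0.894), and Nrp1, a co-receptor of VEGF, 0.824 (0.768 to 0.884). The interferon response list had 19 of 20 members lower, 11 of them with an interval below 1 (median log2 -0.50, -0.73 to -0.39, percentile 0), with Irf1, a transcription factor, at 0.592 (0.527 to 0.665) and the chemokine gene Cxcl10 at 0.471 (0.397 to 0.559). With the stricter cell filter, under which no doublets were called, that median was -0.31 and the Cxcl10 ratio 0.719, and with doublets kept under the usual filter the median was -0.37. Of the TGF-beta signalling list 7 members were higher and 9 lower (median log2 -0.12, percentile 23.7), with the inhibitors of differentiation Id1 at 0.420 (0.276 to 0.630) and Id2 at 0.233 (0.122 to 0.420). The hypoxia and glycolysis list had 11 of 15 members higher, only 3 of them with an interval above 1 (median log2 0.38, percentile 99.8), with Gapdh at 1.66 (1.39 to 1.98). The semaphorin 4D and plexin list had 2 members higher and 5 lower, 1 of these with an interval below 1 (median log2 -0.07, percentile 42.2), with Rhoa at 1.34 (1.12 to 1.60) and Arhgef11 at 0.685 (0.511 to 0.916), both of the pathway through which plexin-B1 acts on the cytoskeleton.

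Cell cycle genes were higher in pericyte-like cells for 9 of 10 measured members (median log2 1.29, percentile 100, and 1.32 with members at 0 UMIs set to their bound). The proliferation marker Mki67 had 2 and 44 UMIs (ratio 17.8, 4.63 to 151), and Top2a, a topoisomerase of dividing cells, 0 and 59 UMIs, at least 15.9-fold higher against a floor of 3 counts. These counts came from few cells: 1 of 102 in Smoke and 3 of 102 in Smoke_CNV held at least 3 UMIs of 13 division genes. Among genes named by size of change, Top2a was joined by Ptprn (0 and 36 UMIs, at least 9.68-fold), Wfdc17 (0 and 34, at least 9.14-fold) and Krt5 (0 and 29, at least 7.80-fold). In Smoke_CNV, Ptprn was most abundant in cone-like cells, Wfdc17 in macrophage-like cells and Krt5 in surface epithelium-like cells. The genes named as lower were Ptgds at 0.131 (0.0748 to 0.216), whose highest level was in RPE-like cells, Plcxd3 at 0.0367 (0.000889 to 0.227, 22 and 1 UMIs), Smoc1 at 0.218 (0.150 to 0.309) and the WNT agonist gene Rspo2 at 0.115 (0.0294 to 0.329).

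In macrophage-like cells, the fourth comparison, genes of the lipid-associated phagocyte and glycolysis lists were mostly higher and most interferon genes lower. All 183 cells in Smoke and 1254 in Smoke_CNV lay in 1 cluster, which does not separate macrophages, monocytes and microglia. A change of cell mix within this class therefore cannot be told apart from expression. The lipid-associated phagocyte list had 13 members higher and 5 lower (median log2 0.78, 0.66 to 0.80, percentile 100). Apoe, the lipid carrier, was 11730 and 20330 CPM (ratio 1.73, 1.71 to 1.76), the lysosomal protease gene Ctsb was at 2.30 (2.22 to 2.39), Fabp5, a fatty acid binding protein, at 3.29 (3.01 to 3.60), and the haem-degrading enzyme gene Hmox1 at 4.43 (3.71 to 5.33). Spp1, osteopontin, was 61.7 CPM in Smoke and 1856 in Smoke_CNV (ratio 30.1, 24.9 to 36.7), though its highest level in both libraries was in pericyte-like cells. Arg1, arginase 1, a marker of wound-type macrophages, went from 1 UMI to 4884 (ratio 479, 86.0 to 18940), and F7, coagulation factor VII, from 0 to 701, at least 22.9-fold higher. The hypoxia and glycolysis list had 13 of 18 members higher (median log2 0.78, percentile 100), with Gapdh at 1.93 (1.78 to 2.09) and Vegfa, the main angiogenic factor, at 6.63 (3.78 to 12.9) from 12 and 811 UMIs. The Vegfa ratio was 3.25 with the stricter cell filter and at least 23.2 after free RNA was subtracted. The median over all genes measured in this class was -0.18 log2, and the trimmed mean scaling differed from the class total by -0.29. Fibroblast markers took 0.00623% of UMIs of macrophage-like cells in Smoke and 0.0546% in Smoke_CNV, and keratin genes 0.00668% and 0.0205%. Ribosomal protein genes took 4.81% and 6.61%.

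Chemokine genes of macrophage-like cells were split, with 15 of 23 members of the chemokine and cytokine list higher (median log2 0.31, percentile 99.8, or 0.28 with members at 0 UMIs at their bound). The monocyte attractants Ccl6 and Ccl8 were at 2.12 (1.99 to 2.27) and 2.80 (2.49 to 3.16), and Il1a, interleukin 1 alpha, at 0.251 (0.218 to 0.289). Ccl5 was at 0.0315 (0.0231 to 0.0424), its highest level in T cell-like cells. The interferon response list had 18 of 21 members lower (median log2 -0.38, percentile 1.04), with Ifit3 at 0.549 (0.486 to 0.620) and Irf1 at 0.591 (0.529 to 0.662). Antigen presentation genes had 10 of 14 lower (median log2 -0.22, percentile 20.7), with Cd74 at 0.790 (0.769 to 0.811) and B2m at 1.10 (1.06 to 1.14). Under the median ratio scaling these medians were -0.20 and -0.04, and the chemokine median 0.49. Cell cycle genes were higher for 19 of 21 members (median log2 1.38, percentile 100), with Mki67 at 2.37 (1.78 to 3.22). Cells with at least 3 UMIs of division genes were 4.37% (1.91 to 8.43) of macrophage-like cells in Smoke and 13.2% (11.4 to 15.2) in Smoke_CNV. Other genes named by size of change were Col3a1 at 48.6, a fibroblast gene here (2.80 with doublets kept), Ccdc192 (38 and 0 UMIs), D7Ertd443e at 0.00841 (0.00166 to 0.0267) and Csmd3 at 0.0456 (0.0390 to 0.0531), a gene most abundant in horizontal-like cells.

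Fibroblast-like cells, the fifth comparison, had higher levels of matrix genes in the Smoke_CNV library. Of the extracellular matrix list 21 of 22 members were higher (median log2 1.66, 1.63 to 1.68, percentile 100). Col3a1 was 1324 and 7642 CPM (ratio 5.77, 5.69 to 5.86), Col1a2 was at 2.60 (2.57 to 2.63), Tnc at 40.8 (36.0 to 46.4), the protease inhibitor gene Timp1 at 18.0 (15.9 to 20.5), and Dcn lower at 0.691 (0.686 to 0.696). The chemokine and cytokine list had 19 of 23 members higher (median log2 1.92, percentile 100), with Il6, interleukin 6, at 3.79 (3.52 to 4.08) and Cxcl10 at 0.301 (0.285 to 0.318). Cell cycle genes were higher for 19 of 21 (median log2 3.26, percentile 100), with Mki67 at 84.2 (44.3 to 184) and Cenpf, a centromere protein, at 68.8 (33.3 to 172). Interferon response genes were lower for 20 of 21 (median log2 -0.89, percentile 0), with Ifit1 at 0.323 (0.310 to 0.336), Irf1 at 0.420 (0.408 to 0.433) and Ifitm3 at 0.960, which turned to 1.15 under median ratio scaling. Genes of the immediate early and dissociation list were lower for 17 of 20 (median log2 -0.50, percentile 0.04), with Fos at 0.519 (0.512 to 0.525) and Klf2 at 0.338 (0.330 to 0.347). This list, shortened to immediate early below, is also named for tissue dissociation, whose part in the difference was not tested.

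Fibroblast-like cells of the 2 libraries sat in different clusters. Clusters were built on the same expression, so values within a cluster do not separate cell mix from expression. Cluster 18 held 746 of the 1551 fibroblast-like cells in Smoke and 358 of 2018 in Smoke_CNV, and cluster 11, rich in Tnfaip6 and Nox4, held 356 and 1072. Within cluster 18 alone the matrix median was 0.65, the chemokine median 0.62, the interferon median -0.38 and the cell cycle median -0.02. There Col3a1 was at 2.24, Tnc at 2.79, Il6 at 1.08 and Mki67 at 3.49. Macrophage markers took 0.0613% of UMIs of fibroblast-like cells in Smoke and 0.303% in Smoke_CNV, Malat1 3.02% and 1.50%, and ribosomal protein genes 5.82% and 8.53%, at a mean depth of 8964 and 18783 UMIs per cell. The median over all genes measured was -0.25 log2 in this class, and under that scaling the immediate early median was -0.25. Genes named by size of change were Hmmr, a gene of dividing cells (0 and 761 UMIs, at least 93.0-fold higher), the collagenase gene Mmp13 at 347 from 1 UMI in Smoke (62.1 to 13700, and at least 89.5 at the finer clustering), Lrrc15, a marker of activated fibroblasts, at 111 (61.9 to 222), and F2rl1, a protease-activated receptor, at 143 (61.4 to 442). In cluster 18 the Lrrc15 ratio was 1.45, and F2rl1 was at least 1.74-fold higher from few UMIs. The genes named as lower were Grin3a at 0.0676 (0.0590 to 0.0771), Sost at 0.0355 (0.0126 to 0.0817), Trpc4 at 0.0965 (0.0738 to 0.125) and Tmprss2 at 0.115 (0.0974 to 0.136).

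Endothelial-like cells, the sixth comparison, had lower levels of the VEGF receptors and far higher levels of cell cycle genes in Smoke_CNV. The cell cycle list had all 21 members higher (median log2 3.63, percentile 100, or 3.19 with members at 0 UMIs at their bound). Top2a had 0 and 339 UMIs, at least 66.7-fold higher, Cenpf 0 and 212, at least 41.7-fold, and Hmgb2 was at 2.88 (2.45 to 3.41). Cells with at least 3 UMIs of division genes numbered 2 (0.510%, 0.0618 to 1.83) in Smoke and 77 (11.8%, 9.39 to 14.5) in Smoke_CNV. In the angiogenesis list 9 members were higher and 13 lower (median log2 -0.21, percentile 6.64). Kdr, the main VEGF receptor, was 1881 and 910 CPM (ratio 0.484, 0.467 to 0.501), Flt1, a second VEGF receptor, at 0.688 (0.673 to 0.703), and Plvap, the diaphragm protein of fenestrae, at 0.386 (0.371 to 0.401). The apelin receptor gene Aplnr was at 7.61 (5.83 to 10.1) and Cxcr4, a tip cell marker, at 4.54 (2.54 to 8.82).

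Junction and barrier genes of endothelial-like cells were mixed, 9 higher and 7 lower (median log2 0.09, percentile 90.8). Cdh5, the adherens junction cadherin, was at 1.44 (1.37 to 1.52), Pecam1 at 1.55 (1.47 to 1.63), Selp, P-selectin, at 4.53 (3.72 to 5.57) and the glucose transporter gene Slc2a1 at 0.342 (0.299 to 0.390). Immediate early and dissociation genes were lower for 17 of 20 (median log2 -0.43, percentile 0.02), with Fos at 0.537 (0.520 to 0.555) and Nr4a1 at 0.427 (0.391 to 0.467). Cluster 20, with the leading gene Plvap, held 318 of the endothelial-like cells in Smoke and 305 in Smoke_CNV, and cluster 10, with the leading gene Fabp4, 74 and 350. A change of cell mix within this class therefore cannot be told apart from expression, for Plvap and the VEGF receptors as well. In cluster 20 alone the angiogenesis median was -0.07, the junction median -0.02, the immediate early median -0.84 and the Aplnr ratio 35.9. Named by size of change were Cfd, an adipocyte-derived complement factor (0 and 455 UMIs, at least 89.5-fold), at least 1.54-fold in cluster 20 alone, where few UMIs were left, and the myeloid genes F13a1 (0 and 339 UMIs, at least 66.7-fold) and Ccl6 at 178 (48.9 to 1469, 14.5 with doublets kept). Macrophage markers made up 0.0163% of the UMIs of this class in Smoke and 0.144% in Smoke_CNV. The genes named as lower were Lrrtm4 at 0.0610, Cntn5 at 0.0609, Fstl5 at 0.0619 and Fam135b at 0.0606, genes most abundant in retinal neurons, and each was closer to 1 with the highest doublet scores removed.

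Müller glia-like cells, the supporting glia of the retina and the subject of the seventh comparison, showed gliosis genes higher for all 19 measured members (median log2 2.96, 2.63 to 3.05, percentile 100). Gfap, the intermediate filament of reactive glia, was 1.22 CPM in Smoke and 99.0 in Smoke_CNV (ratio 81.4, 50.3 to 141). Lcn2, lipocalin 2, was 1.22 and 131 CPM (ratio 108, 66.6 to 186), Vim, vimentin, was at 2.71 (2.60 to 2.82), S100a6 at 7.88 (7.27 to 8.56) and Cp, ceruloplasmin, at 1.77 (1.73 to 1.81). Interferon response genes were higher for all 21 members (median log2 1.29, 1.20 to 1.40, percentile 100), with Ifit3 at 2.38 (2.14 to 2.65) and Ifitm3 at 5.84 (5.33 to 6.41). Antigen presentation genes were higher for 13 of 14 (median log2 1.54, percentile 100), with the class I genes B2m at 2.80 (2.60 to 3.02) and H2-K1 at 75.3 and 226 CPM. The class I gene H2-D1 was at 3.49 (3.10 to 3.92) and turned to at most 0.0815 after rod-estimated free RNA was subtracted, with B2m then at 1.76. Heat shock genes were higher for all 14 members (median log2 0.77, percentile 100), with Hsp90ab1 at 1.58 (1.51 to 1.65) and Cryab at 2.08 (1.97 to 2.19).

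RNA of other kinds also differed in Müller glia-like cells. Haemoglobin genes took 0.327% of their UMIs in Smoke and 0.0164% in Smoke_CNV, and were lower in bipolar-like, cone-like and RPE-like cells as well. Macrophage markers took 0.00964% and 0.0489%. Mitochondrially encoded genes were higher for all 13 members (median log2 1.57, percentile 100), with mt-Atp6 at 3.57 (3.51 to 3.63). Ribosomal protein genes took 0.984% of UMIs in Smoke and 2.24% in Smoke_CNV, and fibroblast markers 0.0128% and 0.101%. In cells matched between libraries on ribosomal protein share, the gliosis median was 2.02, the heat shock median 0.28, the mitochondrial median 0.85 and the antigen presentation median 0.71. Other genes named by size of change were Hmga2, a chromatin protein, at 84.5 (32.1 to 315) and Lox, lysyl oxidase, at 93.6 (31.1 to 461), which is most abundant in fibroblast-like cells and was at least 30.5-fold higher with doublets kept. The genes named as lower were Spc25 at 0.290 (0.276 to 0.305), Dcc at 0.200 (0.150 to 0.262), Il1rapl2 at 0.116 (0.0547 to 0.216) and Il12b with 43 and 0 UMIs, a dendritic-like gene with too few UMIs for a direction when doublets were kept or the cell filter was changed.

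The eighth comparison took the photoreceptors and bipolar cells. In rod-like cells the phototransduction list had 6 members higher and 18 lower, 16 of them with an interval below 1 (median log2 -0.14, percentile 2.74). The median was -0.30 with no cell filter, -0.31 with the stricter filter and at Leiden resolution 0.5, and -0.36 in cluster 1 alone. Sag, rod arrestin, was at 1.34 (1.33 to 1.36) and Gnb3, a cone transducin subunit, at 7.46 (6.90 to 8.07). That median was -0.59 in cells matched one by one on ribosomal protein share, whose summed shares still differed (2.25% in Smoke and 1.90% in Smoke_CNV), and 0.02 after free RNA, estimated from fibroblast, macrophage and keratin genes, was subtracted from Smoke_CNV alone. Immediate early and dissociation genes were higher for all 19 members (median log2 1.23, percentile 100), with Fos at 2.00 (1.84 to 2.17), Socs3, an inhibitor of cytokine signalling, at 4.61 (3.70 to 5.78) and Junb at 3.58 (3.26 to 3.94), and that median turned to -1.38 after the same subtraction. Cluster 1 held 2562 of the 4929 rod-like cells in Smoke and 202 of 1649 in Smoke_CNV, so the class was made of different clusters in the 2 libraries, and in cluster 1 alone the immediate early median was 1.05. Genes named by size of change were Zbtb7c at 108 (66.8 to 186), Edn2, endothelin 2, an injury signal of photoreceptors, at 137 (62.3 to 376), Bcl3, a regulator of NF-kappa B, at 71.8 (38.5 to 151) and Scube1 at 37.7 (23.2 to 65.7). Zbtb7c and Edn2 had their highest level of all classes in rod-like cells of Smoke_CNV. The genes named as lower were the cone opsin gene Opn1sw at 0.142 (0.0853 to 0.222), the Müller genes Spc25 at 0.155 (0.0945 to 0.241) and Glul at 0.251 (0.216 to 0.291), and Calcr at 0.0513 (0.00127 to 0.301, 45 and 1 UMIs).

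In cone-like cells 22 of 24 phototransduction genes were lower (median log2 -0.24, percentile 0, and -0.62 without the genes that name the class), with Arr3, cone arrestin, at 0.624 (0.611 to 0.638) and Opn1mw, the green opsin, at 0.861 (0.840 to 0.883). Rod markers took 0.661% of UMIs of cone-like cells in Smoke and 0.517% in Smoke_CNV, and the free RNA share that rod genes allow reached 100% in both, so less rod RNA in these droplets stays open for the rod genes of that list. Synapse genes of bipolar-like cells were near level with 6 higher and 8 lower (median log2 -0.03, percentile 31.6), among them Nrxn3 at 0.851 (0.843 to 0.859) and Syt1 at 1.13 (1.11 to 1.15), and the median was -0.27 in cells matched on ribosomal protein share.

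RPE-like cells, the ninth comparison, had lower levels of visual cycle genes, which regenerate the chromophore of visual pigments: all 13 measured members were lower (median log2 -0.30, -0.33 to -0.26, percentile 0.435). The isomerase gene Rpe65 was 8616 and 6729 CPM (ratio 0.781, 0.761 to 0.802), Lrat, which makes its substrate, was at 0.684 (0.635 to 0.736), and Ttr, transthyretin, at 0.971 (0.960 to 0.982). That median turned to 0.03 after rod-estimated free RNA was subtracted, with Ttr at 1.21, and was -0.14 with doublets kept. Angiogenesis genes had 5 members higher and 8 lower (median log2 -0.61, -0.83 to 0.09, percentile 0.045), with Vegfa at 205 and 122 CPM (ratio 0.597, 0.489 to 0.723), Flt1 at 0.338 (0.192 to 0.560), which turned to 1.01 with the highest doublet scores removed (list median then 0.03), and Nrp1 at 3.38 (2.22 to 5.16). Serpina3n, an acute phase protease inhibitor, was 1.63 and 447 CPM (ratio 275, 117 to 851), its highest level of any class in Smoke_CNV. The other genes named by size of change are known from other cells: the immune genes Ccr2 (0 and 93 UMIs, at least 92.5-fold), Syk (0 and 61, at least 60.7-fold) and Runx1 at 92.5 (38.8 to 289) were higher, and with doublets kept at least 5.88-fold, at least 9.42-fold and 14.8-fold. The neuronal and glial genes Cntn5 at 0.0241 (0.00290 to 0.0878), Nlgn1 at 0.0539 (0.0196 to 0.119), Adamtsl1 at 0.0599 (0.0193 to 0.142) and Rgs6 at 0.0690 (0.0222 to 0.164) were lower. Macrophage markers took 0.0171% of UMIs of RPE-like cells in Smoke and 0.274% in Smoke_CNV.

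The last comparison followed 1 list, the interferon response, across classes, and its direction differed between them, although free RNA stays open for most retinal classes. It was higher in the neurons, glia and pigment epithelium of the retina: median log2 ratios were 1.72 in rod-like cells (19 of 20 members higher), 1.32 in bipolar-like (20 of 20), 1.31 in cone-like (13 of 15), 1.29 in Müller glia-like, 1.07 in RPE-like (14 of 17) and 0.45 in amacrine-like cells (12 of 17). In rod-like cells the antiviral gene Oasl2 was at 7.84 (5.74 to 10.9) and Usp18, a feedback inhibitor, at 11.5 (6.90 to 20.3). Ifitm3 was at 4.86 (3.82 to 6.22) in cone-like and 3.94 (3.20 to 4.85) in RPE-like cells. The list was lower in most stromal and immune classes, at -0.89 in fibroblast-like, -0.58 in T cell-like (17 of 21 lower), -0.50 in pericyte-like, -0.45 in Schwann-like (17 of 20 lower) and -0.38 in macrophage-like cells. Endothelial-like cells were at -0.19 (9 higher, 12 lower, percentile 8.33), inside the range of random lists, with Irf1 at 0.436 (0.412 to 0.461; 0.270 in cluster 20 alone) and Ifitm3 at 1.40 (1.35 to 1.45). In T cell-like cells keratin genes took 0.00480% of UMIs in Smoke and 0.0842% in Smoke_CNV, haemoglobin genes 0.0248% and 0.276%, the free RNA share that rod genes allow was 15.2% and 42.0%, and the median depth 6956 and 2363 UMIs. Ifit3 was at 0.316 (0.244 to 0.406) in Schwann-like cells, while Ifitm3 was at 3.50 in T cell-like cells and turned to at most 0.541 after rod-estimated free RNA was subtracted. The list was level in smooth muscle-like cells (0.00, 10 of 20 higher) and 0.20 in surface epithelium-like cells (14 of 21 higher), which turned to -0.33 in the larger cluster alone. Irf1 was lower in both, at 0.677 (0.614 to 0.745) and 0.619 (0.575 to 0.667), with Ifitm3 at 1.79 (1.63 to 1.97) in smooth muscle-like and Psmb8, an immunoproteasome subunit, at 1.35 (1.24 to 1.47) in surface epithelium-like cells. Ifitm3 was 291 CPM in Müller glia-like and 1835 CPM in pericyte-like cells of Smoke_CNV.

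Subtraction of free RNA at the highest share that fibroblast, macrophage or keratin genes allow, an alternative chosen after seeing the data, left the interferon median of Müller glia-like cells at 1.22. It turned that of rod-like cells to -2.96 and those of cone-like, RPE-like and amacrine-like cells below 0, and left bipolar-like cells at 0.03. Free RNA was taken off Smoke_CNV alone. By the same rule the shares in Smoke and Smoke_CNV were 35.6% and 13.0% in rod-like and 25.4% and 11.9% in bipolar-like cells. They were 17.4% and 6.45% in amacrine-like, 16.5% and 15.1% in cone-like, and 25.25% and 46.2% in RPE-like cells. The turns of rod-like, amacrine-like and cone-like cells thus rest on correcting only the library with the smaller share. Macrophage markers took 0.0240% of the UMIs of rod-like cells in Smoke and 0.0772% in Smoke_CNV, and fibroblast markers 0.0146% and 0.0637%.

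**Figure D3:**
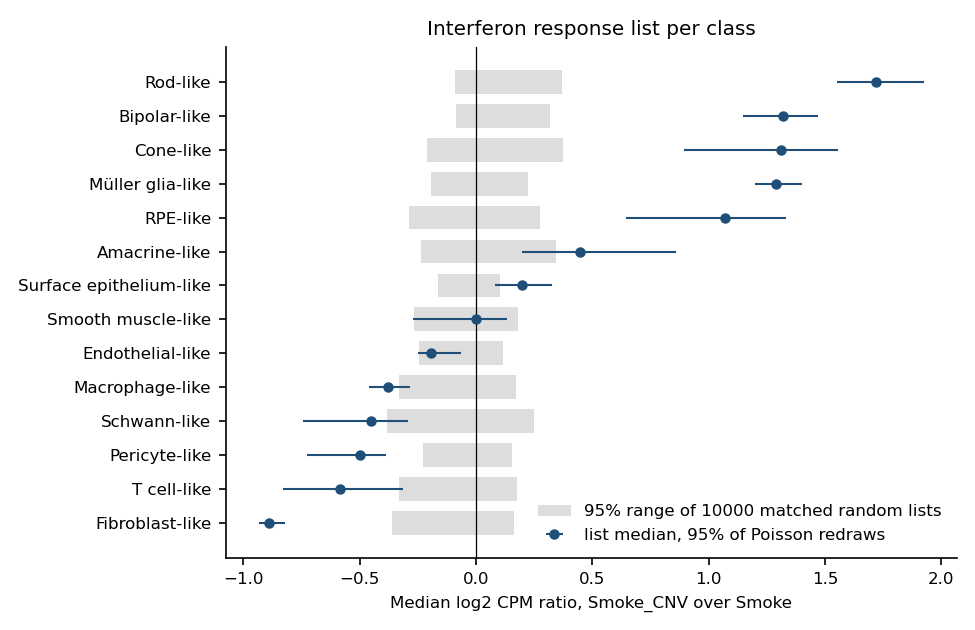
Median log2 CPM ratio (Smoke_CNV over Smoke, 1 library each) of the interferon response list per class, with the 95% range of Poisson redraws (line) and of 10000 matched random lists (grey). Retinal classes lie above 0 and fibroblast-like, T cell-like and pericyte-like cells below.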

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

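The alternatives that removed the highest doublet scores, took the cluster of each class with the most Smoke cells, left surface epithelium-like cells and unnamed clusters out of the denominator, left out naming markers, matched cells on ribosomal protein share, or subtracted free RNA by fibroblast, macrophage or keratin genes were chosen after seeing the data. Of 139 values of 18 class shares under alternatives, 98 stayed within the counting interval and 41 moved. A change of direction was counted only where the main interval left out no difference, and by that rule 0 shares changed direction. The pericyte-like and Schwann-like ratios, whose intervals include 1, lay below 1 without rod-like cells (0.879 for both), the Schwann-like ratio was 1.65 with no cell filter, 1.63 with doublets kept, 1.80 with the highest doublet scores removed and 1.58 without surface epithelium-like cells and unnamed clusters, with intervals above 1, and the pericyte-like ratio was 0.980 at Leiden resolution 2. Of 513 values of 44 list medians, 380 stayed, 122 moved and 11 changed direction. Of 3975 values of 343 gene ratios, 3267 stayed, 684 moved and 24 changed direction. Some values stayed by construction, so these counts overstate stability. The 343 ratios with no minimum and the 319 with at least 50 UMIs repeat the main values. Ratios and medians of classes held in 1 cluster, such as macrophage-like and pericyte-like cells, repeat them in the alternative by largest Smoke cluster. Where a library had 0 UMIs the value is a bound, and it was counted as a change of direction only where the bound itself lay past 1. Thinning moved 51 of 56 shares of cells with a UMI, as fewer UMIs per cell must. Where no cause is named below, the cause was not tested.

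Called doublets changed together with the filter, to 322 in Smoke with no filter and 0 under the stricter one, so these 2 alternatives vary both choices. With no cell filter, the share ratio was 1.75 for fibroblast-like and 0.650 for rod-like cells, the gliosis median of Müller glia-like cells 2.63 and the phototransduction median of rod-like cells -0.30. Cxcl10 turned to 1.16 in smooth muscle-like cells. With the stricter filter, the share ratio was 1.69 for fibroblast-like, 0.314 for Müller glia-like and 0.644 for rod-like cells. List medians were 0.65 for lipid-associated genes in macrophage-like cells, 2.59 for gliosis, -0.31 for interferon genes in pericyte-like cells and -0.31 for phototransduction in rod-like cells. H2-D1 turned to 1.01 in macrophage-like cells.

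At Leiden resolution 0.5, the share ratio was 1.74 for fibroblast-like, 0.321 for Müller glia-like and 0.665 for rod-like cells. The matrix median of fibroblast-like cells was 1.59, the gliosis median 2.63, the interferon median of pericyte-like cells -0.37 and the phototransduction median of rod-like cells -0.31. At resolution 2, the share ratio was 1.72 for endothelial-like, 2.02 for fibroblast-like and 8.16 for surface epithelium-like cells, and the matrix median of fibroblast-like cells 1.85.

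With doublets kept, the rod-like share ratio was 0.422, the matrix median of fibroblast-like cells 1.69, the activation and interferon medians of pericyte-like cells 1.36 and -0.37, and the visual cycle median of RPE-like cells -0.14. Ttr turned to 1.07 in RPE-like cells. With the highest doublet scores removed, the rod-like share ratio was 0.421, the gliosis median 2.59, the activation median of pericyte-like cells 1.49 and the visual cycle median -0.21. In RPE-like cells Flt1 turned to 1.01 and Ttr to 1.02.

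The 2 other denominators of the shares change every share by construction. Without rod-like cells, the ratio was 1.47 for endothelial-like, 1.14 for fibroblast-like, 6.02 for macrophage-like, 0.281 for Müller glia-like, 0.879 for pericyte-like, 0.277 for RPE-like and 7.42 for surface epithelium-like cells. Without surface epithelium-like cells and unnamed clusters, these were values of the share ratio: Rod-like cells 0.527, endothelial-like 2.63, fibroblast-like 2.05, macrophage-like 10.8, Müller glia-like 0.504, pericyte-like 1.58 and RPE-like 0.497.

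In the cluster of each class with the most Smoke cells, fibroblast-like ratios turned to 0.813 for Hmgb2, 1.06 for Ifitm3, 0.664 for Myc, 1.79 for Plxnb1 and 0.953 for Stmn1. Gad1 turned to at most 0.799 in bipolar-like cells, a bound from 0 UMIs whose counting interval includes 1. By Angiogenesis list median: Endothelial-like cells were at -0.0699, and at -0.0189 for junction genes. By Cell cycle list median: Fibroblast-like cells were at -0.0230, and at 0.65 for matrix genes. The median of phototransduction in rod-like cells was -0.36 and that of interferon genes in surface epithelium-like cells -0.33.

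Scaling by the trimmed mean moved every ratio of a class by the same factor. In fibroblast-like cells it turned Cxcl1 to 1.01 and Ifitm3 to 1.18, and in macrophage-like cells H2-D1 to 1.16 and Psmb8 to 1.09, with Sema4d at 0.774. Scaling by the median ratio turned Ifitm3 to 1.15 in fibroblast-like cells, and H2-D1 to 1.07 and Psmb8 to 1.01 in macrophage-like cells. Medians were then 1.92 for matrix genes in fibroblast-like, 0.96 for lipid-associated genes in macrophage-like and -0.22 for phototransduction in rod-like cells.

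With free RNA subtracted at the share that rod genes allow, Plxnb1 turned to at least 4.46 in fibroblast-like, H2-D1 to at most 0.0815 in Müller glia-like and Ifitm3 to at most 0.541 in T cell-like cells, and in RPE-like cells Abca4 to 1.01, Rgr to 1.02 and Ttr to 1.21. By Angiogenesis list median: Endothelial-like cells were at -0.0287, and by Visual cycle list median: RPE-like cells at 0.0338. Other medians were 1.55 for matrix in fibroblast-like, 3.48 for gliosis in Müller glia-like and 0.30 for activation in pericyte-like cells. It was not run for amacrine-like, bipolar-like and cone-like cells, where the share exceeded 50% in at least 1 library, nor for rod-like cells, whose own genes set it. With the subtraction by fibroblast, macrophage or keratin genes, from Smoke_CNV alone, values turned for the Interferon response list median: Cone-like cells were at -3.88, rod-like at -2.96 and amacrine-like at -0.64. The same held for the Interferon response list median: RPE-like cells were at -2.61. The gliosis median was 2.61, the visual cycle median 0.34 and the immediate early median of rod-like cells -1.38. By Phototransduction list median: Rod-like cells were at 0.0168.

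Without naming markers, medians were -0.10 for angiogenesis in endothelial-like, 1.95 for matrix in fibroblast-like, 1.26 for activation in pericyte-like and -0.20 for phototransduction in rod-like cells. In cells matched on ribosomal protein share, they were 2.02 for gliosis, -0.23 for the visual cycle and -0.59 for phototransduction in rod-like cells. Over members with at least 50 UMIs the activation median of pericyte-like cells was 0.67. Over whole libraries, Sema4d was at 1.19 without rod-like cells, and with equal weight per class at 0.952, with Plxnb1 at 0.934 and Cd72 at 0.886. A prior of 2 UMIs moved 0 of 44 medians. A minimum of 50 UMIs or none decides which gene ratios are kept and cannot move them.

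No paired analysis was possible because each group had 1 library. The alternatives for values that cannot be turned into counts did not apply, since counts were recovered.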

Other observations

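The tests of interferon genes and of the macrophage-like share were chosen after the result was seen. The predictions for cell cycle genes were written before their test results, but for a pattern already seen. The doublet test among them uses the removal of the highest doublet scores, an alternative chosen after seeing the data. In Schwann-like cells, the myelinating glia of peripheral nerve with 77 cells in each library, the 4 genes named as higher in Smoke_CNV were Ccl2, Lcn2, Thbs1 and Gap43. The monocyte attractant gene Ccl2 had 1 and 229 UMIs (ratio 139, 24.8 to 5528, and 19.99 with doublets kept). Its highest level was in macrophage-like cells, whose markers took 0.0318% of UMIs of Schwann-like cells in Smoke and 0.128% in Smoke_CNV. Gap43, a growth cone protein, had 3 and 208 UMIs (ratio 42.2, 14.2 to 206). Lcn2 had 0 and 119 UMIs, at least 24.1-fold higher, with too few UMIs for a direction when doublets were kept or no cell filter was used, and Thbs1, thrombospondin, 0 and 112, at least 22.7-fold. Lower were Adamts16 (35 and 0 UMIs) and the neuronal and cone genes Asic2 at 0.0285, Arr3 at 0.0277 and Pde6h at 0.0294, while rod genes took 0.275% and 0.0593% of UMIs of these cells.

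Cells with at least 3 UMIs of 13 division genes differed between classes. In Smoke_CNV they were 27.0% of dendritic-like, 10.7% of surface epithelium-like, 8.92% of fibroblast-like and 2.56% of T cell-like cells. In Smoke they were 23.9%, 16.1%, 0.451% and 9.38%. Depth differs between the libraries, and free RNA adds such UMIs to cells that do not divide. Of whole libraries, Plxnb2 was 30.8 and 74.4 CPM (ratio 2.42, 2.31 to 2.53), Plxnc1 57.7 and 42.4 (0.735), Cd72 4.05 and 11.2 (2.75) and Plxnb1 27.5 and 19.6 (0.713). With equal weight per class the Cd72 ratio turned to 0.886, and Plxnb1 was at 0.934 and Plxnb2 at 1.42. Of Plxnb1 UMIs, surface epithelium-like cells gave 11.8% in Smoke and 50.4% in Smoke_CNV.

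The first pattern was the higher interferon response in retinal classes. Free RNA of stromal, immune and epithelial cells was tested by subtracting the Smoke_CNV library's mean profile, from that library alone, at the highest share that fibroblast, macrophage or keratin genes allow. In Müller glia-like cells the median log2 ratio stayed at 1.22 (1.03 to 1.29), above the 95% range of random lists (up to 0.19), which argues against free RNA as the whole cause. With the subtraction by rod genes, at 14.4% in Smoke and 22.6% in Smoke_CNV, it was 1.33, while H2-D1 of the antigen presentation list fell to at most 0.0815. In rod-like cells it was -2.96 (-3.35 to -2.41) at the highest share, 13.0%, and 0.92 (0.76 to 1.46) at the lowest, 5.64%, above random lists (up to 0.25). The share assumed thus decides the outcome, and in rod-like cells free RNA cannot be told apart from expression. By the same rule the highest share of rod-like cells in Smoke was 35.6%, which was not taken off. More cytoplasmic RNA per cell was tested in cells matched on ribosomal protein share: the medians were 1.79 (1.56 to 2.00) in rod-like and 1.08 (0.84 to 1.19) in Müller glia-like cells, above random lists in both. In matched rod-like cells the summed share was 2.25% in Smoke and 1.90% in Smoke_CNV, so more such RNA in Smoke_CNV was not left, which argues against it as the whole cause there. In 393 matched Müller glia-like cells per library it was still 1.38% and 1.99%, and in this class more cytoplasmic RNA cannot be told apart from expression. A response to the laser injury, which the design names, stays open for Müller glia-like cells as a hypothesis that was not tested, as do differences between the animals or preparations of the 2 libraries.

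The second pattern was the larger macrophage-like share. If it came from fewer retinal cells alone, the shares of all other classes would rise alike. Macrophage-like cells per pericyte-like cell had a ratio of 6.85 (4.93 to 9.50), which restates shares already seen. Whether the pericyte-like cells came from retina or choroid is not known here. The share ratio was 1.54 (1.44 to 1.65) for fibroblast-like and 8.11 (6.94 to 9.53) for macrophage-like cells. These shares, also seen before, argue only against fewer retinal cells as the sole cause. Macrophage-like cells per surface epithelium-like cell had a ratio of 0.811 (0.626 to 1.05). Both shares had been seen before this test, so it does not speak for more ocular surface tissue in the Smoke_CNV preparation, which cannot be told apart from recruitment by the laser injury. That recruitment was not tested and stays open.

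The third pattern was the higher level of cell cycle genes in endothelial-like and fibroblast-like cells. Free RNA of dividing cells would give all classes a like level, but the summed division genes in Smoke_CNV were 14.7 times (12.2 to 17.7) those of Müller glia-like cells in endothelial-like and 12.4 times (10.4 to 14.9) in fibroblast-like cells. The gap depends on the class compared. RPE-like cells of Smoke_CNV held 203.5 CPM of these genes, though 3 of 195 cells had at least 3 such UMIs. Endothelial-like cells held 372.4 CPM, fibroblast-like cells 314.3, rod-like cells 52.7 and Müller glia-like cells 25.4. With the highest doublet scores removed, the medians were 3.53 (2.89 to 4.63) and 3.18 (2.75 to 3.85), above random lists, whose upper ends were 0.20 and 0.01. The medians argue against doublets with high scores as the whole cause. Against free RNA as the whole cause the values argue with Müller glia-like and with rod-like cells as the reference. With RPE-like cells the gap was smaller, and free RNA cannot be excluded by it. Cells with at least 3 division UMIs were 1.54% (0.318 to 4.43) of RPE-like, 11.8% of endothelial-like and 8.92% of fibroblast-like cells of Smoke_CNV. RPE-like cells were shallower, at a median of 3080 UMIs, so these shares do not decide it either. Fibroblast-like cells with division UMIs in Smoke_CNV had a median doublet score of 0.0689 against 0.0485 for the class and were deeper, and Scrublet called 0 doublets in that library, so doublets without high scores stay open. Endothelial-like cells with division UMIs in Smoke_CNV lacked these signs. Their median doublet score was 0.03705, as in the class, and their median depth 4560 UMIs against 6240. Division after laser injury stays open as a hypothesis, which was not tested in other libraries.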
